A study of Mus musculus with 7 samples.

How the data were processed

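Long-term haematopoietic stem cells (LT-HSCs), the bone marrow cells that can rebuild the whole blood system over the long term, were sorted from female Emcn-/- mice and their Emcn+/+ littermates and profiled by RNA sequencing. Emcn encodes endomucin, a sialomucin of the cell surface. Per the labels' protocols, marrow from the hind leg bones was depleted of lineage-positive cells, stained with antibodies to Gr-1, CD11b, B220, CD3e, Ter119, Sca-1, c-kit, CD16/CD32, CD150 and CD48, and sorted with a dead cell dye, and each replicate held 3000 to 5000 cells of a single mouse. Libraries were made with a SMARTer stranded total RNA kit for very small inputs, which primes without regard to a poly(A) tail, whereas the molecule label reads polyA RNA. They were sequenced in pairs on a NextSeq 500, per the same protocols.

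The deposited table holds estimated counts per gene as whole numbers, with no scaling between libraries. The submitters' processing notes name cutadapt and Salmon without versions. The annotation, the step from transcripts to genes and the rounding are not given in the sources used here. All 7 value columns matched a sample by name and 0 were left unused. Of 54347 gene identifiers, 98.1% were present with the same version in GENCODE M21 (GRCm38), which gave positions and missing symbols, and 99.5% without the version. The identifiers outside it held 0.0292% of all counts. A symbol shared by several genes was kept with its identifier, and 167 symbols were shared in this way.

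Samples were grouped by the genotype label into 4 WT (Emcn+/+) and 3 KO (Emcn-/-) libraries, named here by genotype and mouse number as in the labels (wt_284). Mouse numbers are unique and the labels name no pairing, so none was fitted. An effect of litter was therefore not tested. The lowest mouse numbers, 284 and 290, are both WT, so litter or age could follow genotype in part. The labels name no batch or sort day. Library totals ran from 6444134 to 11101774 counts. The counts were compared with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust quasi-likelihood test, KO minus WT, Benjamini-Hochberg adjustment, threshold 0.05), and 15372 of the 29739 genes with any count were tested. Standard errors are the log2 fold change divided by the square root of the quasi-likelihood F, and 95% intervals follow from them. Levels are CPM, counts scaled to a common library size with the TMM factors. Lists of genes fixed before the data were examined were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for the 28 lists with at least 5 tested genes, with Benjamini-Hochberg adjustment over the lists. A list level is the mean log2 CPM of its tested members in a library. Shares of the library were compared by a two-sided exact permutation test over the 35 splits of 7 libraries into 4 and 3, whose smallest p is 0.0286. The counting interval of Emcn is the exact binomial 95% interval, and the limit for a count of 0 is 3 counts. Intervals and limits cover counting error only, since the reads carry no molecular identifiers in the values used here.

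Genes are named by a rule set before the data were examined. It takes Emcn, up to 12 passing genes in each direction whose groups do not overlap and whose mean is at least 2 CPM, filled to 10 by the smallest p where fewer pass, up to 4 passing members of each list filled to 3 by p, and a set of sort and stem cell genes whatever their p. Of what the rule takes, 1 called list with its 3 genes and 2 other genes are not reported here, although the list stays in the counts of lists. Transcripts named as leading markers of other marrow cells, and genes called by another tool, were chosen after their values were seen.

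The fit was tested on simulated data in which 200 of 15372 genes were changed between KO and WT. It recovered 1.20% of 1.5-fold changes, 16.0% of 2-fold changes, 55.6% of 4-fold changes and 66.0% of 8-fold changes. Above 10 CPM these shares were 1.97%, 23.7%, 80.7% and 89.9%. Of the simulated calls, 7.96% were unchanged genes, which is above the nominal 5% that the threshold of 0.05 stands for, and without wt_284 it was 13.6%. The simulation without wt_284 kept the gene levels and spread estimated from all 7 libraries, so it does not describe the spread of the remaining libraries. With no gene changed, at most 1 gene was called in any of 5 runs. A list of 30 genes shifted 1.5-fold was called, and 0 of 27 unchanged lists were. The simulated genes vary independently, so this does not test lists whose members vary together.

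Alternatives set before the data were examined were DESeq2 1.42.0, RLE and upper-quartile normalization, no filter, a filter of 1 CPM in 3 libraries, a fit that is not robust, limma-voom with quality weights, 1 surrogate variable from sva 3.50.0, only mice numbered above 300, another threshold, leaving out each mouse, and for lists an estimated correlation and fry. Added after seeing the data were a term for libraries wt_284, wt_290 and ko_306, the myeloid list level as a covariate, only libraries wt_310, wt_312, ko_314 and ko_320, DESeq2 without wt_284, and the list tests with that term or without wt_284 at an estimated correlation. Figures were drawn with matplotlib 3.10.9.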

Results

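The data describe gene expression in sorted LT-HSCs of 4 WT and 3 KO mice. The comparison asks what changes in these cells without Emcn, a gene that the series title ties to quiescent stem cells and to their passage through endothelium. Library totals were 9155059 counts for wt_284, 10322741 for wt_290, 6444134 for wt_310 and 7701933 for wt_312. They were 11101774 for ko_306, 6648881 for ko_314 and 8071035 for ko_320. Between 18507 and 23317 genes had at least 1 count in a library. Every library was well above the sampling noise of the others, with a chi-square per degree of freedom of at least 7.61 in each pair.

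Emcn (ENSMUSG00000054690.17, a protein-coding gene on the plus strand of chromosome 3 from 137341067 to 137432185 in GRCm38) was nearly absent from the KO libraries. WT libraries held 130, 327, 223 and 216 counts of it, and KO libraries held 1, 0 and 0. The level was 27.1 ± 8.0 CPM (SD, n = 4) in WT and 0.0287 ± 0.0497 CPM (SD, n = 3) in KO. Over the pooled counts KO stood at 0.145% of WT, with an exact 95% counting interval from 0.00368% to 0.812%. Which exons the allele removes is not given in the sources used here, so where the 1 KO count arose stays open. A count of 0 allows up to 0.451 CPM in ko_314 and 0.372 CPM in ko_320. wt_284 had the lowest WT level, 15.8 CPM, against 27.7 to 34.1 CPM in the other WT libraries. The adjusted p was 1.1e-04 in edgeR, with a fitted log2 fold change of -9.02 that depends on the prior count. Limma-voom with quality weights gave an adjusted p of 0.981 with a log2 fold change of -8.32, and the other alternatives kept the call.

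**Figure D1:**
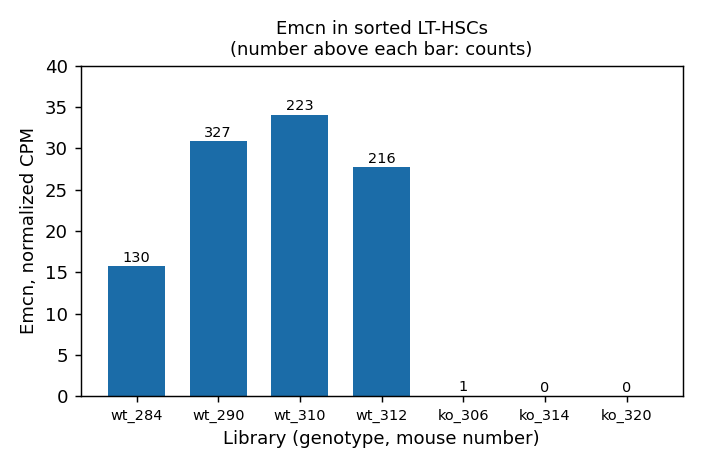
Emcn in each library, as bars of normalized CPM by genotype and mouse number, with the number of counts above each bar. The 4 WT libraries lie between 15.8 and 34.1 CPM, and the 3 KO libraries hold 1, 0 and 0 counts.

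Apart from Emcn, no gene passed the threshold between KO and WT. Of 15372 genes tested in edgeR, 0 were higher and 1 was lower in KO, and the next smallest adjusted p was 0.992. At an unadjusted p under 0.05 there were 503 genes, 197 higher and the rest lower, where 768.6 would be expected by chance. WT and KO values did not overlap for 4.86% of genes, against 5.71% expected by chance. DESeq2 called 10 genes, all lower in KO. Without wt_284 edgeR called 3 genes, and with no filter on low counts it called 81, of which 5 were higher and 76 lower. With mice above 300 it called 7, of which 4 were higher and 3 lower. The fit with no filter tested 29739 genes, and 1779 had an unadjusted p under 0.05. It gave Emcn an adjusted p of 3.4e-36 at a log2 fold change of -9.01. Its p can thus be far smaller than in the main fit at nearly the same fold change. Calls of single genes from it, given below, are therefore weak support. For 49.6% of genes, and 76.5% of those above 10 CPM, the 95% interval of the fold change lay within 2-fold in either direction.

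The 10 tested genes within 1000 kb of Emcn on either side included 0 calls, with log2 fold changes from -0.65 to 0.40 and a smallest adjusted p of 0.861 over these 10 genes. They include Ppp3ca, a calcineurin subunit, at 0.15 ± 0.16 (SE), and Dapp1, an adaptor of B cell signalling, at 0.09 ± 0.14 (SE).

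The genes with the smallest p in each direction did not pass, and their values follow without a call. Among genes with higher KO values were Hmgn3, a nucleosome-binding protein, with a log2 fold change of 1.03 ± 0.22 (SE), Mtif2, a mitochondrial translation initiation factor, at 0.70 ± 0.20, and Dnm1l, a GTPase of mitochondrial division, at 0.51 ± 0.16. Hmgn3 stood at 26.9 CPM in WT and 55.2 CPM in KO, and every KO library was above every WT library. Zfp760, Exosc7, Uprt, Rbm34, Zfp386, Tbca and Efl1 had log2 fold changes from 0.56 to 1.08. Among genes with lower KO values were the sodium pump subunits Atp1b2, at -4.70 ± 1.09, and Atp1b1, at -3.17 ± 0.77, and the choline dehydrogenase Chdh, at -4.67 ± 1.30. Atp1b1 stood at 19.0 CPM in wt_284, at 4.34 to 5.2 CPM in the other WT libraries and at 0.509 to 1.29 CPM in KO. Pkhd1l1, Irs2, Hvcn1, Pik3ap1, Crat and the histone gene H2bc11 had log2 fold changes from -1.70 to -0.68. Hvcn1 went from -1.70 to -1.13 without wt_284, and Crat from -1.28 to -1.91 without ko_306. All 19 genes of these sets apart from Emcn had an adjusted p of 0.992 in the main edgeR fit. With no filter edgeR called Hmgn3 (0.0170), Pkhd1l1 (0.00218) and H2bc11 (0.0241) among them. DESeq2 called Atp1b2, Atp1b1 and Chdh, with adjusted p of 0.0126, 0.0426 and 0.0426, and edgeR with no filter called them too (0.00314, 0.0265 and 0.00218). DESeq2 without wt_284 called none of the 3, with log2 fold changes of -4.09, -2.38 and -3.62 and a smallest adjusted p of 0.569. Without ko_306 Chdh went to -8.80, as the other KO libraries held 0 counts of it.

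Stem cell identity genes showed no call. Of 37 tested members of that list, 22 had positive and 15 negative log2 fold changes, 0 passed over all genes and 0 adjusted over the list alone, and the list had an adjusted p of 0.230 in camera. Kit, the receptor of stem cell factor used in the sort, stood at 640 CPM in WT and 701 CPM in KO, a log2 fold change of 0.13 with a 95% interval from -0.25 to 0.51. Slamf1, which encodes CD150, had 0.16 (-0.43 to 0.75), Ly6a, which encodes Sca-1, had -0.17 (-0.79 to 0.45), and Procr, the endothelial protein C receptor, had 0.39 (-0.14 to 0.91). As c-kit, CD150 and Sca-1 were stained for the sort, similar levels of Kit, Slamf1 and Ly6a may in part be set by the gating. Gata2 had 0.23 (-0.08 to 0.54) and Cd82 had -0.53 (-1.20 to 0.14). Vwf, a gene of platelet-biased stem cells, had 0.17 (-0.29 to 0.63), and Selp, which encodes P-selectin, had -0.09 (-0.72 to 0.53). Without wt_284 the values were 0.03 for Kit, 0.01 for Slamf1, -0.27 for Ly6a, 0.15 for Gata2, -0.15 for Cd82, 0.05 for Vwf and -0.17 for Selp, and the list turned lower (adjusted p 0.650). Slamf1 turned to -0.20 with 1 surrogate variable and to -0.27 with the myeloid level as a covariate.

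Homing and adhesion genes, the group closest to passage through endothelium, showed no call either. Of 40 tested members, 17 had positive and 23 negative log2 fold changes, 0 passed over all genes and 0 adjusted over the list alone, with a list adjusted p of 0.50. Itga4, an integrin subunit that binds VCAM-1, had -0.17 (-0.50 to 0.16), and Cxcr4, the receptor of CXCL12, had -0.72 (-2.10 to 0.67). Itgb2 had -1.83 (-4.28 to 0.62), with 484 CPM in wt_284 against 58.4 to 76.4 CPM in the other WT libraries. Itgb7 had -1.37 (-3.18 to 0.45). Of 8 tested genes in a list of sialomucins, the family of Emcn, and other glycoproteins of the cell surface, 2 had positive and 6 negative log2 fold changes and the list adjusted p was 0.436. Cd34 had 0.06 (-0.39 to 0.51), Cd164 had -0.29 (-0.75 to 0.18), Cd24a had -0.90 (-2.14 to 0.35) and Emb had -0.51 (-1.33 to 0.30). Without wt_284 the values shrank to -0.08 for Cxcr4, -0.47 for Itgb2, -0.17 for Itgb7, -0.13 for Cd164, -0.30 for Cd24a and -0.07 for Emb, and Cd34 turned to -0.05. The unadjusted edgeR p fell there for Itgb2 (0.114 to 0.0301) and Cd24a (0.128 to 0.113). It rose for Cxcr4, Itgb7, Cd164, Emb and Cd34, and each of these genes had an adjusted p of 0.999. Cxcr4 turned to 0.47 with 1 surrogate variable, and with the myeloid level as a covariate Cxcr4 (0.64), Itgb2 (0.05), Itgb7 (0.13), Cd164 (0.14), Cd24a (0.08) and Emb (0.27) all turned positive. The myeloid level was itself higher in WT than in KO in 11 of 12 pairs of libraries. As a covariate it can thus take up part of a genotype difference. Sign changes with it, here and for other genes, do not show an opposite effect of genotype.

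**Figure D2:**
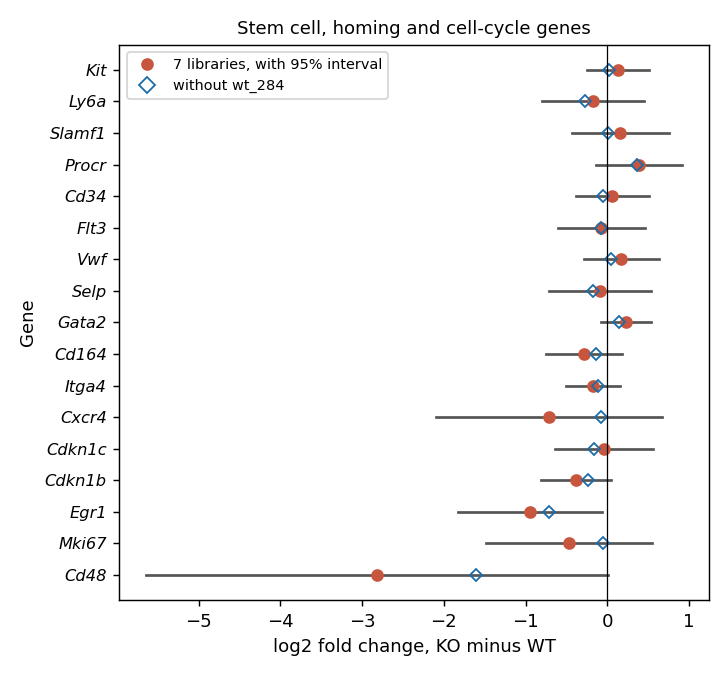
Log2 fold change, KO minus WT, of 17 stem cell, homing and cell-cycle genes, with 7 libraries (filled circles, bars are 95% intervals) and without wt_284 (open diamonds). Of the genes plotted, the interval of Egr1 alone leaves out 0, from -1.82 to -0.06. Its adjusted p is 0.992, or 0.0315 by edgeR with no filter.

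The quiescence list and the G2 and mitosis list were lower in KO by the test with a preset correlation, and neither was called with an estimated one (adjusted p 0.716 for both). The quiescence list had 7 positive and 23 negative members, a median log2 fold change of -0.32 and an adjusted p of 0.00319, and 0 members passed over all genes or adjusted over the list alone. Egr1, an immediate-early transcription factor, had -0.94 ± 0.39 (SE), Nr4a1, a nuclear receptor of the same response, had -1.77 ± 0.82, and Cdkn1b, which encodes the inhibitor p27, had -0.38 ± 0.20. Cdkn1c, which encodes p57, had -0.04 (-0.64 to 0.56). The G2 and mitosis list was lower at an adjusted p of 0.0321, with 6 positive and 38 negative members. Mki67 had -0.47 (-1.49 to 0.55), Aurka had -0.70, Ube2c had -1.01 and Ckap2 had 0.42. Without wt_284 that list was not lower, with an adjusted p of 0.917. The S phase list had 13 positive and 27 negative members and an adjusted p of 0.548, with Ccne1 at -1.36, Rfc3 at 0.64 and Clspn at -0.33. Without wt_284 the values were -0.71 for Egr1, -0.46 for Nr4a1, -0.24 for Cdkn1b, -0.16 for Cdkn1c, -0.05 for Mki67, -0.44 for Aurka, -0.39 for Ube2c and -0.87 for Ccne1. The S phase list turned higher there (adjusted p 0.808). EdgeR with no filter and all libraries called Egr1 and Nr4a1 (adjusted p 0.0315 and 0.0379). Nr4a1 was high in wt_284 alone, at 50.7 CPM. It stood at 6.42 to 8.12 CPM in the other WT libraries and at 3.95 to 7.23 CPM in KO. With the myeloid level as a covariate Nr4a1 turned to 0.05 and Ube2c to 0.10, and with 1 surrogate variable Mki67 turned to 0.25.

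A further 6 lists, of mature and committed marrow cells, early progenitors and sort antigens, were lower in KO by the same test. None of them was called with an estimated correlation (adjusted p 0.716 for each). In each of them wt_284 was the highest and wt_312 the lowest WT library. The myeloid list had 1 positive and 40 negative members, a median log2 fold change of -2.30, or -1.25 without wt_284, and an adjusted p of 2.16e-12 that rose to 0.716 with an estimated correlation. Of these members 9 are also in other lists, and 18 reached 1 CPM in every library. Mpo, the myeloperoxidase of granule-forming cells, had -5.51 ± 1.66 (SE), Irf8 had -2.67 ± 0.87 and Ly86 had -4.18 ± 1.44. Mpo stood at 1084 CPM in wt_284, at 27.2 to 203 CPM in the other WT libraries and at 5.42 to 8.95 CPM in KO. The erythroid list had 2 positive and 28 negative members, a median of -1.23 (-0.757 without wt_284), an adjusted p of 1.29e-07 and 24 members that reached 1 CPM in every library, with the haem synthesis gene Cpox at -1.38 and with Trim10 at -3.29. The mast cell and basophil list (adjusted p 0.00760) had Mcpt8 at -3.92, Prss34 at -3.63 and Cpa3 at -2.10. Of its 9 tested members 3 reached 1 CPM in every library. The summed CPM of this list was 945 to 1156 in WT and 928 to 1138 in KO. Kit and Gata2, which are also in this list, made up most of it (793 and 280 CPM in wt_290). The sum therefore says little about mast cells and basophils. Mcpt8 and Cpa3 were each lower in every KO library than in every WT library, while Prss34 overlapped. The lymphoid list (adjusted p 0.0363) had Cd74 at -0.66, Blnk at -2.49 and Satb1 at -0.74. The multipotent progenitor list had an adjusted p of 0.0370 and shares Mpo, Cd48 and Satb1 with the others. The sort antigen list had an adjusted p of 0.0322, with Fcgr2b at -2.82 and Fcgr3 at -5.04, which encode CD32 and CD16, and Cd48 at -2.82 (-5.64 to 0.01). It also holds the stem cell markers Kit, Ly6a and Slamf1, whose values are given above. Flt3 had -0.07 (-0.60 to 0.46). In these 6 lists 0 members passed over all genes or adjusted over the list alone. Among the members named here, edgeR with no filter called Cpox (0.0293), Mcpt8 (0.00168), Ly86 (0.0336) and Fcgr2b (0.0228). Without wt_284 the values shrank to -3.76 for Mpo, -1.48 for Irf8, -0.86 for Cpox, -2.05 for Trim10, -0.23 for Satb1, -1.87 for Fcgr2b, -2.87 for Fcgr3 and -1.61 for Cd48. Ly86 and Blnk no longer passed the filter. The unadjusted edgeR p fell there for Mpo (0.0197 to 0.0106), Irf8 (0.0183 to 0.00418), Cpox (0.0223 to 0.00672), Trim10 (0.0332 to 0.00801) and Fcgr3 (0.0580 to 0.0321). It rose for Satb1, Fcgr2b and Cd48, and each of these genes had an adjusted p of 0.999. Without ko_306 Ly86 went to -8.46, Mcpt8 to -9.21 and Prss34 to -9.99. The other KO libraries held 0 CPM of these 3 genes, so the size of these values depends on the prior count. Without ko_320 Cpa3 went to -3.13. With the myeloid level as a covariate Blnk turned to 0.59.

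The myeloid level, in mean log2 CPM, was 6.75 in wt_284, 3.73 in wt_290, 3.77 in wt_310 and 1.52 in wt_312. It was 2.75 in ko_306, 1.24 in ko_314 and 1.02 in ko_320, so ko_306 lay above wt_312. The exact permutation test of the 2 genotypes gave a two-sided p of 0.143 for this level and 0.257 for the erythroid level. Without wt_284 the myeloid (adjusted p 3.62e-07), erythroid (5.81e-05), mast cell and basophil (0.0280), quiescence (0.0452) and ribosomal protein (0.0353) lists stayed called in the same direction with the preset correlation. With an estimated correlation none of them was called without wt_284, with adjusted p of 0.928 for ribosomal protein genes and 0.844 for the other 4. The 7 fits that each left out 1 mouse used the preset correlation. The myeloid, erythroid and mast cell and basophil lists were called in 7 of them, and the quiescence list in 6 (not without ko_314, 0.156). The lymphoid list and the G2 and mitosis list were called in 3, and the multipotent progenitor and sort antigen lists in 2.

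**Figure D3:**
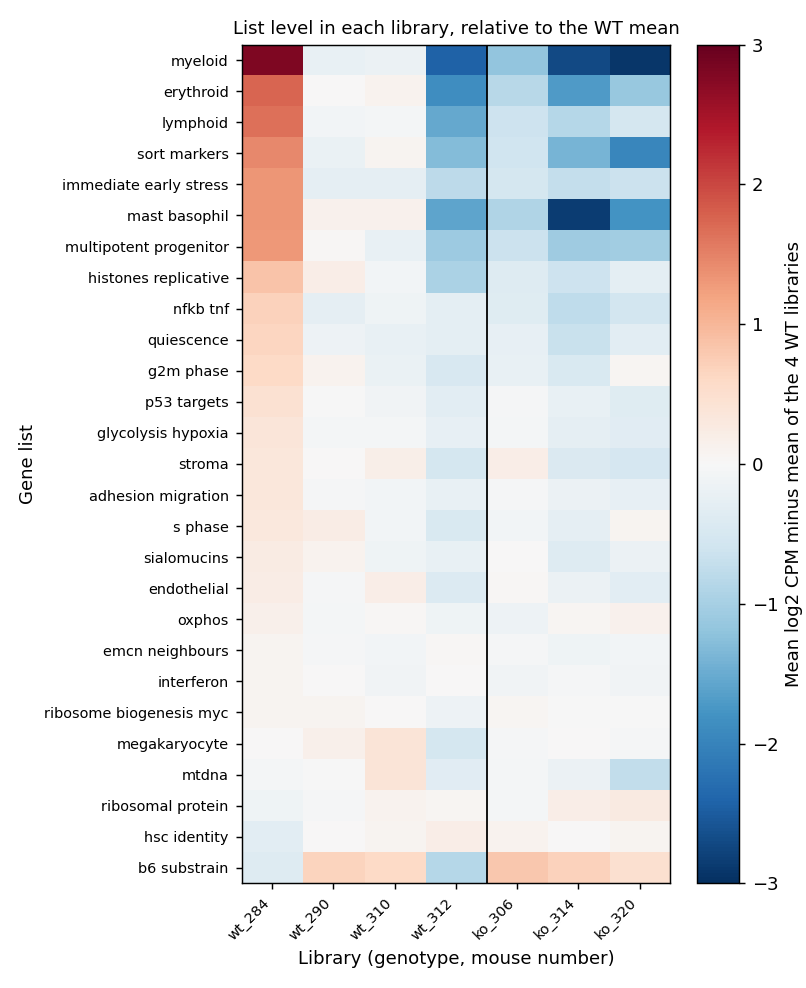
Level of each of 27 gene lists in each library, as the mean log2 CPM of its members minus the mean of the 4 WT libraries, by colour. Myeloid, erythroid and lymphoid genes are highest in wt_284 (myeloid 2.81 above the WT mean), and wt_312, at -2.42, lies near ko_314 and ko_320.

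Stress, signalling and metabolic lists were lower in KO at the preset correlation and had the same adjusted p of 0.716 with an estimated one. The immediate-early and heat-shock list (adjusted p 7.91e-05) had 4 positive and 35 negative members, with Fosl2 at -1.17 and Atf3 at -5.98. Its level was 6.55 in wt_284, 4.43 to 4.95 in the other WT libraries and 4.51 to 4.70 in KO. The NF-kB and TNF list (0.00590) had Rel at -0.86, Cxcl2 at -5.18 and Il1b at -5.06. Replicative histone genes (0.000249) had 0 positive and 27 negative members, with H2ac6 at -0.69, H2bc3 at -0.64 and H2bc11 at -0.99. Glycolysis and hypoxia genes (0.0321) had Eno1 at -0.64, Slc16a3 at -3.14 and Gpi1 at -0.44. None of these 4 lists was called without wt_284. The values there were -0.41 for H2bc3, -0.40 for Eno1, -1.66 for Slc16a3 and -0.20 for Gpi1, and Atf3, Cxcl2 and Il1b did not pass the filter. Without ko_306 the values were -9.34 for Cxcl2, -9.64 for Il1b and -5.07 for Slc16a3. The other KO libraries held 0 CPM of Cxcl2 and Il1b, so the size of those values depends on the prior count. In these lists 0 members passed over all genes or adjusted over the list alone. Among the members named here, edgeR with no filter called Slc16a3 (0.00649) and H2bc11 (0.0241).

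Ribosomal protein genes were higher in KO by the preset test. Of 79 members 70 had positive and 9 negative log2 fold changes, the median was 0.15 and the adjusted p was 0.000142, or 0.716 with an estimated correlation. Rpl31 had 0.37 ± 0.14 (SE), Rpl24 had 0.41 ± 0.16 and Rps6 had 0.29 ± 0.16. Their share of all counts was 5.17% ± 0.746 (SD, n = 4) in WT and 5.82% ± 0.691 (SD, n = 3) in KO, with an adjusted p of 0.471 in the exact permutation test. By library it was 4.14% in wt_284, 5.10% in wt_290 and 5.04% in ko_306 against 5.68% to 6.34% in the other 4, so it also followed a split of the libraries that cuts across genotype, and 2 of the 3 low libraries are WT. The list was not called without ko_320 (adjusted p 0.0808).

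The other lists were not called, and 0 of their members passed over all genes or adjusted over the list alone. Adjusted p was 0.190 for interferon genes, 0.615 for p53 targets, megakaryocyte, endothelial, Emcn neighbour and substrain genes, 0.586 for stroma, 0.767 for nuclear respiratory chain genes, 0.280 for mitochondrial genome genes and 0.476 for ribosome biogenesis. Among interferon genes Oas3 had -0.74 ± 0.26 (SE) and Irf7 had -0.71 ± 0.26. In the megakaryocyte list Rgs18 had 0.55 and Plek had -1.23, or -0.62 without wt_284, where Oas3 had -0.44. The mean and the median of the megakaryocyte list (-0.03 and 0.05) and of the mitochondrial genome list (-0.33 and 0.15) differed in sign, and camera gave both as higher. Nnt, which differs between the C57BL/6 substrains, is split here between overlapping gene models, so its value is uncertain. The level of the substrain list, of 5 tested genes, was 5.12 in wt_284 and 4.65 in wt_312, against 5.99 to 6.32 in the other libraries. Its mean log2 fold change was 0.65 and its median 0.09. The cause was not tested.

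No share of the library passed in the exact permutation tests, in which a single share separated fully by genotype would reach an adjusted p of 0.171 and so could not pass. Mitochondrial genome genes took 13.0% ± 1.48 (SD, n = 4) of counts in WT and 14.3% ± 1.33 (SD, n = 3) in KO, with an adjusted p of 0.471. Haemoglobin genes took 0.136% ± 0.162 in WT and 0.0244% ± 0.00769 in KO, with 0.377% in wt_284 (adjusted exact p 0.471). Replicative histone genes took 0.333% ± 0.105 in WT and 0.257% ± 0.0371 in KO (adjusted exact p 0.471). The 10 most abundant genes took 18.7% ± 1.02 in WT and 18.8% ± 1.37 in KO, and 21017 ± 2260 genes were detected in WT against 20292 ± 2525 in KO (both adjusted exact p 0.743).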

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

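The weighing of the lists and of wt_284 rests on tests chosen after the values were seen, except the counts of splits, the thinning and the removal of wt_284 from the library split, and the quiescence list without immediate-early genes, which were set before their results. Among the 4 WT libraries, 28 of 142 values had 1 library farther from the others than Dixon's 95% limit allows. wt_284 was that library in 25 of them. For normally distributed values not chosen from these data, chance flags about 1 in 20, or 7.1 here. Gene values were CPM without a log, many genes were named by their p in these data, and members can vary together. The 7.1 is therefore not a firm baseline for the 28. The group of 3 KO libraries was not tested.

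Genes of mature marrow cells and of their surface were high in wt_284. It held Mpo at 1084 CPM, Irf8 at 89.9 CPM, Itgb2 at 484 CPM, Itgb7 at 53.7 CPM, Fcgr3 at 88.0 CPM, Fcgr2b at 24.4 CPM, Cd24a at 696.6 CPM, Cd36 at 25.6 CPM, Vcan at 15.3 CPM, Blnk at 9.82 CPM, Satb1 at 71.3 CPM and Hvcn1 at 33.3 CPM. Response genes were high there too, with Nr4a1 at 50.7 CPM, Atf3 at 30.1 CPM, Cxcl2 at 34.7 CPM, Il1b at 41.2 CPM and Oas3 at 84.9 CPM, and the quiescence and NF-kB lists reached levels of 5.98 and 5.27. Metabolic and cell-cycle genes at an extreme in wt_284 were Slc16a3 at 35.3 CPM, Gpi1 at 424 CPM, Chdh at 18.9 CPM, Atp1b1 at 19.0 CPM, Ccne1 at 30.2 CPM and Rfc3 at 22.7 CPM. The other 3 values were Exosc7 at 32.7 CPM in wt_290, Efl1 at 33.0 CPM in wt_312 and Rpl24 at 254 CPM in wt_310.

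The lower myeloid and erythroid lists in KO may reflect other marrow cells in some sorted samples, a genotype effect, or reads carried between libraries. S100a9, an abundant neutrophil transcript, stood at 3497 CPM in wt_284, at 50.0 to 348 CPM in the other WT libraries and at 19.0 to 161 CPM in KO, although the sort removed cells with Gr-1, CD11b, B220, CD3e and Ter119. Reads of wt_284 carried into wt_290 and wt_310, as the whole source of these genes, would keep 1 ratio for all genes. The ratio was 2.03 times as high for erythroid as for myeloid genes in wt_290 and 2.94 times in wt_310. The 95% intervals over genes were no lower than 1.41, which argues against carried reads as the whole source. Carried reads beside other cells in these libraries were not tested. For ko_306 carried reads as the whole source of these genes are argued against too. They would set a floor under every gene, and the counts of the 41 members, Mpo in the first place, allow at most 0.723% of the wt_284 level, below the interval of the median myeloid ratio (2.31%, 1.05% to 3.54%), and Igkc held 0 counts where 31.0 would be carried. Earlier forms of this test had left it open, with an erythroid to myeloid ratio of 1.36 (0.573 to 3.39) and with 3 of 41 members under the floor against a bound of 4. Reads carried into a KO library would also raise KO. Other cells in wt_284 alone would not raise these genes in other libraries. The myeloid level was 3.73 in wt_290, 3.77 in wt_310 and 2.75 in ko_306, against 1.02 to 1.52 in wt_312, ko_314 and ko_320. With carried reads argued against as the whole source, these levels argue against wt_284 as the only library with such transcripts. Whether wt_284 alone gave the difference between genotypes was not decided. Other cells in several samples to different degrees and the loss of Emcn cannot be told apart. The myeloid median without wt_284 was still -1.25, while the list had an adjusted p of 0.844 with an estimated correlation. The exact permutation p between genotypes was 0.143, with WT above KO in 11 of 12 pairs of libraries. In the remaining pair, ko_306 exceeded wt_312, with S100a9 at 161 against 50.0 CPM and Ltf at 107 against 14.0 CPM.

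wt_284, wt_290 and ko_306 differed from the other 4 libraries in 16 genes (edgeR), 15 of them lower, among them Rpl37, Rpl13a, Rpl26, Rps24, Kcnq1ot1 and Rpph1. This split cuts across genotype, the only group in the design, so no biological explanation from the design was tested. Depth is argued against as the cause, since thinning all libraries to the smallest total gave 25 genes, which include all 16. Other cells in wt_284 are argued against as well, since without wt_284 there were also 25 genes, 13 of them shared. Nuclear rRNA genes took 4.25% of counts in wt_284, 2.18% in wt_290 and 1.64% in ko_306, against 0.993% to 1.60% in the other 4. After thinning, 21774 to 22110 genes were detected in these libraries, against 18307 to 19760 in the other 4. A difference in library preparation or sort day stays open, as the labels name neither.

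The quiescence list may be lower in KO because of the immediate-early genes in it or because of wt_284, and these cannot be told apart from a genotype effect. Without its 6 immediate-early members the adjusted p was 0.0233 and without wt_284 it was 0.0452, both with the preset correlation, against 0.716 and 0.844 with an estimated one. Without both it was 0.157, with a median log2 fold change of -0.15.

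Of the 35 splits of the 7 libraries into 4 and 3, 5 called as many genes as the 1 of the genotypes, and the highest other gave 16, so chance is not excluded for the count. The split that gave 16 was that of wt_284, wt_290 and ko_306, which points to a structure of the samples, and with that split as a term edgeR still called 1 gene, Emcn. The split of wt_312, ko_314 and ko_320 from the rest called 6 genes. It had 2049 genes at an unadjusted p under 0.05, against 1853 for wt_284, wt_290 and ko_306. Since it groups ko_314 and ko_320 with wt_312, it overlaps genotype in part, and no term for it was fitted. Emcn itself was called in 1 of the 35 splits, the real one. For the lists, 5 of 35 splits called as many as the 14 of the genotypes, and the highest other called 15. Each of the 35 splits called at least 1 list, and the median was 8. List calls with the preset correlation were therefore common whatever the split, and chance is not excluded for them either. In the 14 called lists the estimated correlation ran from 0.0722 (sort antigens) to 0.712 (replicative histones), above the preset one in each. Adjusted p with the preset correlation thus assume less correlation between members than was estimated.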

How the results depend on the processing

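Emcn kept its direction in all 20 alternatives and its call in 19, with log2 fold changes from -10.81 to -8.32. Limma-voom with quality weights lost it, with a log2 fold change of -8.32 and an adjusted p of 0.981. The count of changed genes was 1 with RLE, upper-quartile normalization, the CPM filter, the fit that is not robust, a threshold of 0.1 and a 2-fold minimum. It was 10 with DESeq2, 81 with no filter, 0 with limma-voom, 2 with 1 surrogate variable and 7 with mice above 300 (4 higher, 3 lower). Leaving out each mouse gave 1 to 3 genes. Of the alternatives chosen after seeing the data, the count was 1 with the term for wt_284, wt_290 and ko_306, 2 with the myeloid level as a covariate, 10 with only wt_310, wt_312, ko_314 and ko_320 (6 higher, 4 lower), and 6 with DESeq2 without wt_284. The cause of these differences was not tested. The 14 list calls were 0 with an estimated correlation, 0 with fry, 1 with mice above 300 and 5 to 16 when each mouse was left out, 5 of them without wt_284 and 8 without ko_314. After seeing the data, they were 9 with the added term and 0 with an estimated correlation without wt_284. Leaving out each mouse moved the adjusted p of G2 and mitosis from 4.88e-05 to 0.917. Called lists that turned from lower to higher, none called where they turned, were G2 and mitosis (0.917 without wt_284, 0.153 with mice above 300, 0.977 with an estimated correlation without wt_284) and, with mice above 300, lymphoid (0.912) and replicative histones (0.912). Of 210 values of the lists not called, 22 had the other direction, among them S phase (0.808 without wt_284), and 4 were called with 1 mouse left out (S phase 0.00703 and 0.0333, stem cell identity 0.0159, mitochondrial genome 0.0258). Of 2007 values of the other named genes, 54 changed sign and 19 were called. No share passed with all genes or with filtered genes. The fit recovers mainly large changes, with 16.0% of simulated 2-fold changes recovered, or 23.7% above 10 CPM, and a common coefficient of variation between libraries of 44.5%. The simulation did not vary depth.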

Other observations

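The genes here were chosen after their values were seen. DESeq2 called, besides Emcn, Ear1 and Alox15, expressed in eosinophils and other myeloid cells, and Mpo, among others, with log2 fold changes of -10.49, -5.68 and -5.50 and adjusted p of 0.00615, 0.0285 and 0.0126. Ear1 was also called by edgeR with 1 surrogate variable (0.00974) and with the myeloid level as a covariate (0.0158), and by DESeq2 without wt_284 (1.97e-05). Mpo was also called by edgeR with only mice above 300, at -2.79 and an adjusted p of 0.0200, and by DESeq2 without wt_284, at -3.75 and 0.00761. The latter fit also called the haemoglobin gene Hbb-bt, at -1.43 and 0.0135. Over the alternatives edgeR and limma-voom gave no call for Mpo with all 7 libraries. Without wt_284 edgeR called Gm49342 lower, at -9.21, and Fam177a2 higher, at 9.66, both with an adjusted p of 0.0326, and both were also called with mice above 300 and by DESeq2 without wt_284. Gm49342 had 4.72 to 12.7 CPM in the other WT libraries and 0 CPM in wt_284 and KO, and Fam177a2 had 3.76 CPM in wt_284, 0 CPM in the other WT libraries and 4.39 to 23.7 CPM in KO.

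Immunoglobulin transcripts were concentrated in wt_284. Igkc stood at 115.5 CPM there, at 0.128 to 2.45 CPM in the other WT libraries and at 0 CPM in KO, and Ighm stood at 113 CPM there and at no more than 6.04 CPM elsewhere. Neutrophil granule transcripts followed, with Ltf at 2775 CPM in wt_284, 182 CPM in wt_290, 107 CPM in ko_306 and 1.40 CPM in ko_320. The first principal component of log2 CPM held 36.2% of the variance. It placed wt_284 (-97.8) at one end and wt_312 (62.0), ko_320 (57.4) and ko_314 (47.9) at the other, with ko_306 at -12.1.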
